A study of Homo sapiens with 9 samples.

How the data were processed

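Total RNA of 3 breast epithelial cell lines of the MCF-10A series (MII, MIII and MIV) was measured on Affymetrix arrays with biotin-labelled cRNA, 3 arrays per line. The deposited values are intensity values: 1 MAS5 signal per probe set and array on a linear scale, per the submitters' processing notes. The software version and detection calls were not given in the sources used here. The values show that each array had been scaled to the same trimmed mean, since the mean of the middle 96% of values was close to 500.07 on every array. No further scaling was applied. The table held 54675 probe sets without missing values, of which 62 were controls. The array annotation lists 1 gene for 41091 probe sets, several genes for 1801 and no gene for 11721. Gene numbers of 41037 probe sets were matched to a reference table of the human assembly GRCh38.p14, which changed 0 symbols and served otherwise to place genes in genome order.

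Signals were tested as log2(signal + offset), with an offset of 18.3, the pooled 25th percentile of all values. A gene was kept if at least 3 of the 9 arrays exceeded the pooled median of 69.3, and each of the 19775 genes was represented by its probe set with the highest mean signal; 10523 genes had more than 1 probe set. This left 12594 genes. A group-means model was fitted to all 9 arrays in limma 3.58.1 (R 4.3.3) with an intensity trend in the variance prior, which leaves 6 residual degrees of freedom, and p-values were adjusted by Benjamini-Hochberg over all genes tested. A gene was called at an adjusted p under 0.05 and a change of at least 2-fold. Genes lower or higher in MIV than in both other lines carry both calls in the same direction. Genes lost at the floor are those of the lower group whose 3 MIV arrays all lie under the pooled median while the means of MII and MIII lie above it. Their number was set beside the overlap of independent lists and beside simulated unchanged groups compared with shared MIV arrays. Errors of signals are SDs over 3 arrays and errors of log2 changes are standard errors from limma.

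The 28 gene lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists within each comparison. The lists cover caveolae, epithelial junctions, mesenchymal and EMT genes, basal, luminal and keratinocyte differentiation genes, desmosomes, interferon response, antigen presentation, NF-kB cytokines, proliferation, cyclin-dependent kinase inhibitors with the 9p21 genes, MAPK output, extracellular matrix, proteases, integrins, reported metastasis suppressors, TGF-beta and BMP targets, Wnt, hypoxia and glycolysis, cholesterol and fatty acid synthesis, the unfolded protein and amino acid stress response, p53 targets, apoptosis, oxidative stress, fibroblast markers, leukocyte and endothelial markers, and housekeeping controls. Each list was also tested with a correlation estimated from the data and with fry, whose directional test asks whether the members move one way on balance and whose mixed test asks whether they change in either direction. The directional fry test called 26 lists in MIV against MIII, 25 in MIV against MII and 26 in MIII against MII, and the mixed test called 28 in each.

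Named genes were chosen by rule: CAVIN2 with all its probe sets; per comparison the 10 largest rises and 10 largest falls on the offset scale among called genes whose arrays did not overlap; the 15 largest falls and 10 largest rises in MIV by the smaller of both changes; and up to 4 called members per list with the largest change, or the member with the smallest p where none was called. This rule, the lists and the tests of the comparisons between lines were fixed before the data were examined, while several tests of explanations and the genes that fell or rose at both steps were chosen afterwards. Probe sets with several genes or none were not named. No named gene had another tested probe set called in the opposite direction.

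The fit was tested on simulated data with 200 changed genes. With a true log2 change of 1, 54.5% of them were called in MIV against MIII and 48% in MIV against MII. That change lies at the 2-fold minimum itself, which limits the share called, and 87% and 86% had a limma adjusted p under 0.05. With a change of 1.5 the shares called were 92% and 92.5%, and with a change of 2 they were 99% and 98.5%. In a simulation with 1 list shifted by 0.5, camera called 1 of 28 lists, the shifted one. The simulated genes varied independently, so this does not test false calls among correlated genes. Alternatives tried were an offset of 1 or of the pooled median, quantile and cyclic loess normalization, scaling to the same median of the tested genes, no filter, a filter at the pooled 75th percentile of 435.7, a variance prior without trend, array weights, the mean of all probe sets of a gene, the highest-mean suffix-free probe set (without _s_at, _x_at or _a_at), a block for the replicate number, the arrays of the lines compared alone, other thresholds, and each array left out in turn. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 prepared the tables and drew the plots.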

Results

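Total RNA of 3 human breast cell lines was measured on 1-colour Affymetrix arrays, with 3 arrays per line and 9 arrays in all. The lines belong to the MCF-10A series, derivatives of a non-tumorigenic breast epithelial line that carry activated HRAS. By their labels, MII (MCF-10AT1Kcl2) represents carcinoma in situ, MIII (MCF-10A1h) carcinoma and MIV (MCF-10A1a) metastatic carcinoma. The labels call the arrays of a line biological replicates but do not say whether they came from separate cultures, so p-values measure the spread between these arrays, which may be technical in part. The median signal per array lay between 69.0 and 71.7 in MII, between 72.1 and 74.9 in MIII and between 64.7 and 65.2 in MIV. The number of arrays limits the precision, and the median standard error of a log2 change was 0.11. Across probe sets, which are not independent replicates, arrays of the same line correlated at a mean r of 0.983, against 0.949 between MII and MIV, 0.924 between MIII and MIV and 0.921 between MII and MIII. One array stood apart in its hybridisation controls: MIV replicate 3 gave a bioB spike-in signal of 3685, against 1235 to 1879.6 on the other arrays. Each of the 12594 genes tested was represented by its probe set with the highest mean signal. Fold changes on the log2(signal + offset) scale understate the change of dim genes.

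The series was set up to find genes whose expression is lost in the metastatic line, and its title names SDPR, now CAVIN2. CAVIN2, a protein that coats caveolae and helps to shape them, was high in MII, intermediate in MIII and near the floor in MIV. On the brighter of its probe sets, which is suffix-free, its signal was 1125 ± 138 in MII, 598 ± 58.8 in MIII and 14.1 ± 11.2 in MIV (SD, n = 3 arrays each). On the other probe set (suffix _s_at) the signal was 637 ± 105 in MII, 345 ± 20.5 in MIII and 38.4 ± 19.4 in MIV. Both probe sets lay below the pooled median signal of 69.3 on all 3 MIV arrays. In limma, CAVIN2 had a log2 change of -5.20 ± 0.23 (SE) in MIV against MII (adjusted p = 5.89e-10) and of -4.31 ± 0.23 in MIV against MIII (adjusted p = 2.18e-09). The second probe set gave -3.59 ± 0.23 and -2.74 ± 0.23, with limma adjusted p of 4.64e-08 and 4.04e-07 over all probe sets. Between MIII and MII the log2 change of CAVIN2 was -0.89 ± 0.23 (limma adjusted p = 0.0054), short of the 2-fold minimum for a call. The exact two-sided permutation test gave p = 0.1 in each of these comparisons, the smallest value that 3 arrays against 3 can give.

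**Figure D1:**
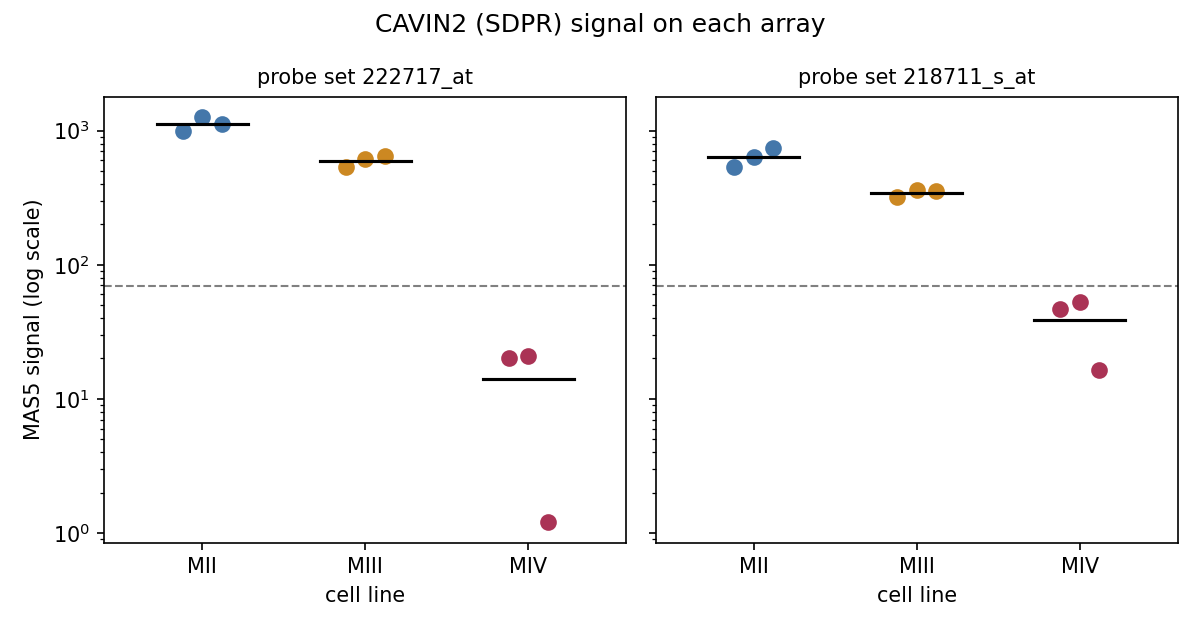
CAVIN2 (SDPR) signal on each of the 9 arrays, on a log axis in MAS5 signal units, for both probe sets of the gene; points are arrays, black bars are means of 3 arrays and the dashed line is the pooled median signal of 69.3. The MIV arrays lie below the dashed line on both probe sets, with means of 14.1 and 38.4, and every MII and MIII array lies above it.

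As a list, the proteins of caveolae were not called in any of the 3 comparisons. Of 10 tested members of the caveolae list, CAVIN2 alone was called in MIV against MIII, where the list median was -0.21 (camera adjusted p = 0.668). Against MII, CAVIN2 and the receptor ROR1 (-1.05 ± 0.10) fell in MIV, and the list had a median of 0.025 but a mean of -0.54 and a test direction of down (adjusted p = 0.829). In MIII against MII the called member was EHD2, which stabilises caveolae at the membrane, with a log2 change of 1.09 ± 0.07, and the list median was -0.37 (adjusted p = 0.277). The ROR1 and EHD2 calls were lost when all probe sets of a gene were averaged, with values of -0.43 and 0.86.

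Genes lower in MIV than in both other lines numbered 302, CAVIN2 among them, and 123 of these were at the floor in MIV, with all 3 MIV arrays under the pooled median and the means of MII and MIII above it. On the log2(signal + offset) scale, the smaller of both falls was largest for MYADM, a membrane protein of lipid rafts, with signals of 2676 ± 229.9 in MII, 2611 ± 194 in MIII and 43.7 ± 19.8 in MIV (SD, n = 3) and log2 changes of -5.50 ± 0.19 and -5.46 ± 0.19. PYCARD, the adaptor of the inflammasome, went from 706 ± 132 in MII and 711 ± 38.6 in MIII to 4.5 ± 2.3 in MIV. Signals this far under the pooled median do not rank these falls by ratio. The metallothionein MT1E, which binds zinc and copper, fell from 23619.5 and 26251 to 1082 ± 139.8. The signal of its probe set (suffix _x_at) thus remained bright in MIV. TIMP3, an inhibitor of matrix metalloproteinases, fell from 976 ± 113 and 1866 ± 90.0 to 35.2 ± 7.1. ACAT2, the cytosolic thiolase that makes acetoacetyl-CoA for sterol synthesis, fell from 2876 ± 198 and 1460.1 ± 62.5 to 71.0 ± 16.6, measured by a single probe set. EMP3, a tetraspan membrane protein, fell from 1719 ± 81.6 in MII and 9127 ± 353 in MIII to 92.5 ± 26.8. The estrogen sulfotransferase SULT1E1, the homeodomain-only protein HOPX and the G protein subunit GNG2 ended at 20.6 ± 4.9, 8.7 ± 5.2 and 10.8 ± 5.5 in MIV, with log2 changes against MII of -3.50 ± 0.14, -3.51 ± 0.17 and -3.35 ± 0.19. The list of the 15 largest such falls was completed by SECTM1, AGMAT, BASP1, CDH19 and EVA1C, whose smaller fall of the pair lay between -3.79 and -3.19. AGMAT did not fall on its highest-mean suffix-free probe set, which gave 0.20 against MII and 0.21 against MIII.

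**Figure D2:**
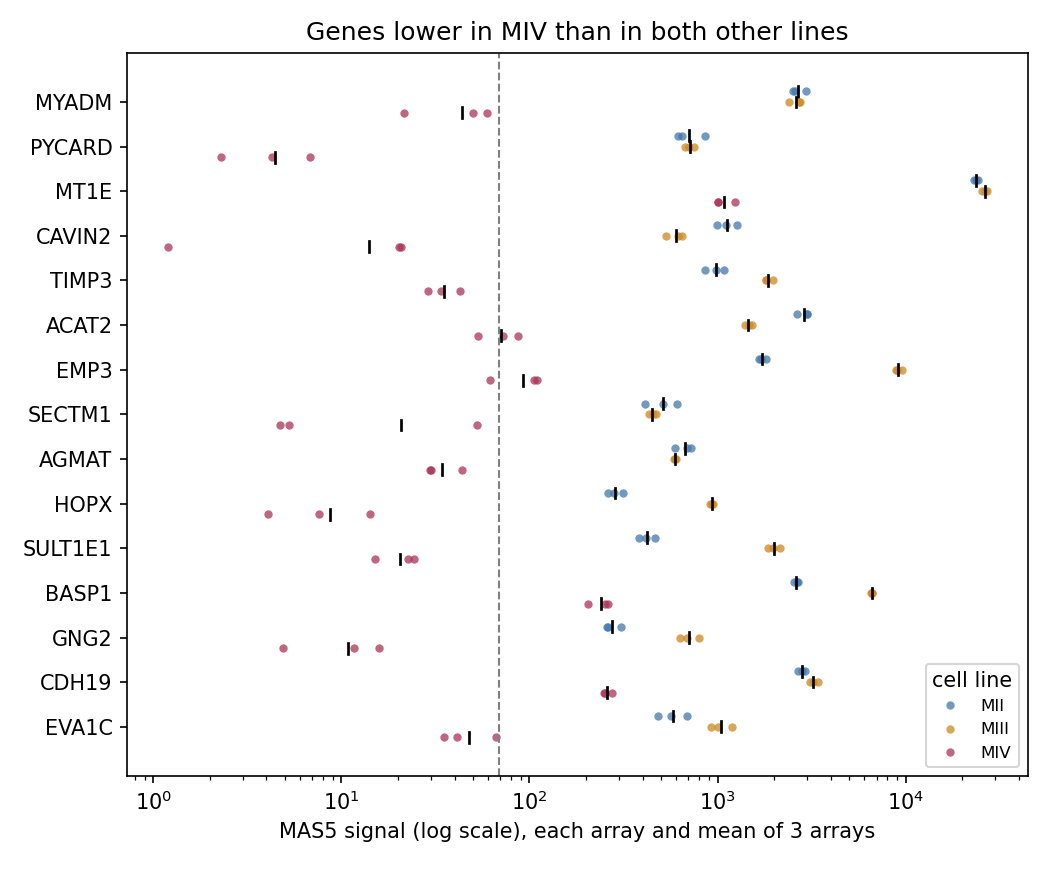
MAS5 signal on each array, on a log axis, of the 15 genes with the largest falls in MIV against both other lines on the offset scale; points are arrays, black bars are means of 3 arrays and the dashed line is the pooled median signal of 69.3. The means of MYADM lie at 2676 in MII, 2611 in MIII and 43.7 in MIV, while MT1E stays above the dashed line in MIV at 1082.

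Genes higher in MIV than in both other lines numbered 125. On the offset scale the smaller of both rises was largest for the uncharacterised LOC389831, which went from 44.1 ± 16.2 in MII and 57.8 ± 1.5 in MIII to 1910.0 ± 360.0 in MIV (SD, n = 3). RNF128, a membrane ubiquitin ligase, rose by 3.36 ± 0.19 and 4.28 ± 0.19 in log2, and the non-coding LINC03040 by 3.13 ± 0.38 and 4.06 ± 0.38. IL13RA2, a decoy receptor of interleukin 13, rose from 948 ± 59.4 and 2107 ± 88.7 to 15168 ± 256. The calcium-dependent phosphodiesterase PDE1C rose by 4.92 ± 0.26 against MII and 2.80 ± 0.26 against MIII, and the DNA polymerase POLM by 2.79 ± 0.13 and 3.54 ± 0.13. HMGCS1, which condenses acetoacetyl-CoA into HMG-CoA, rose from 1910.1 ± 92.0 and 1079 ± 156 to 11231 ± 1070.1. INSIG1, a sterol-sensing regulator of the same pathway, rose from 2381 ± 183 and 1537 ± 31.0 to 10609 ± 303. INSC and IL17RD completed the 10 largest, with smaller rises of 2.30 ± 0.19 and 2.14 ± 0.12. Independent lists of the same lengths would share 50.8 lower and 18.5 higher genes of the 12594 tested. Unchanged groups simulated against shared MIV arrays gave 0 of either in 100 simulations. No gene was changed in those simulations, so almost no calls arose, and that 0 does not measure what long lists share. Both comparisons use the same MIV arrays, which are too few to divide, so part of the excess may come from the shared arrays. With the offset set to the pooled median, 164 genes were lower and 83 higher than in both lines, and 55 were at the floor.

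**Figure D3:**
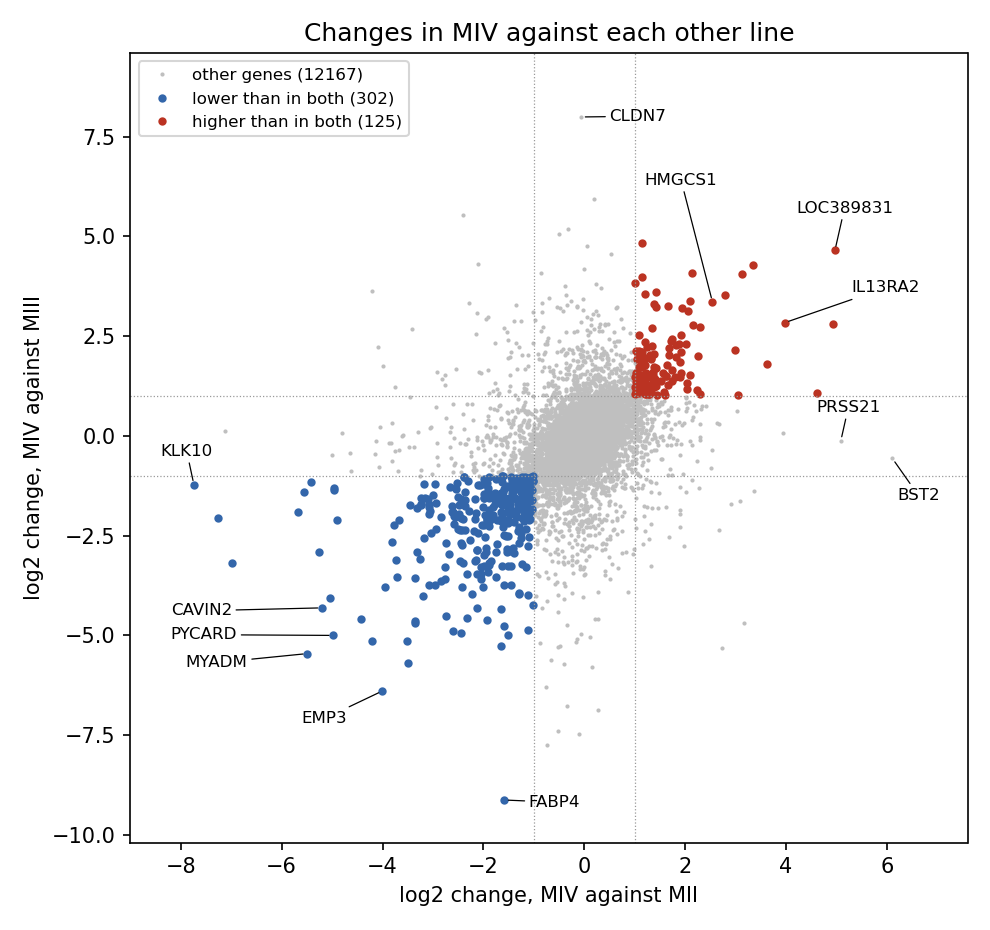
Log2 changes of the 12594 tested genes in MIV against MII (horizontal) and against MIII (vertical), with the 302 genes lower than in both lines in blue, the 125 higher than in both in red, all others in grey, and dotted lines at the 2-fold minimum. CAVIN2 lies at -5.20 and -4.31, while FABP4 lies at -1.59 and -9.13.

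MIV was then compared with MIII, the metastatic against the other carcinoma line. The epithelial junction list was higher in MIV than in MIII (camera adjusted p = 3.61e-17), and the mesenchymal (2.62e-13) and extracellular matrix (1.89e-09) lists were lower. CLDN7, a claudin of tight junctions, had a signal of 9825 ± 780.4 in MIV and 23.5 ± 21.8 in MIII (SD, n = 3), a 255-fold rise on the offset scale. FABP4, a fatty acid carrier typical of adipocytes, had 11.6 ± 14.3 in MIV and 15664 ± 228 in MIII, a 561-fold fall on that scale. The log2 change was -7.76 ± 0.20 for the fatty acid receptor CD36, -7.47 ± 0.31 for the growth factor binding protein IGFBP4 and -7.41 ± 0.32 for the collagen COL6A1.

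Of the 12594 genes, 1604 were called between MIV and MIII, of which 623 rose in MIV and 981 fell (61.2%). The share of falls varied with the setting, from 51.2% without a fold minimum and 51.4% under the filter at the pooled 75th percentile to 67.0% at an adjusted p under 0.01 and 4-fold. Among the called genes, 99% had the 3 arrays of one line all above the 3 of the other, as had 58.8% of all genes tested, where chance gives 10%. The remaining largest falls were those of SRGN, ENPP2, EMP3, POSTN, GNG11 and CCN3, between -6.88 and -5.72. The small GTPase RAB25, which acts in epithelial recycling, rose by 5.93 ± 0.07, the surface antigen PSCA by 5.53 ± 0.19, the keratin KRT15 by 5.19 ± 0.07 and the tight junction genes CLDN4 and OCLN by 5.07 ± 0.18 and 4.76 ± 0.25. BSPRY, LOC389831, the membrane protease PRSS8 and GABRP rose by 4.84, 4.65, 4.57 and 4.31.

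The epithelial junction and identity list rose in MIV against MIII, with 17 of its 22 tested members up, 0 down and a median of 2.18 (camera adjusted p = 3.61e-17). The mesenchymal and EMT list fell, with 17 of 22 down, 0 up and a median of -2.59 (adjusted p = 2.62e-13). Its called members included SPARC (-5.31 ± 0.14), the neuronal cadherin CDH2 (-4.87 ± 0.17) and WNT5A (-4.77 ± 0.36). In the extracellular matrix list 17 of 30 fell and 0 rose (median -1.24, adjusted p = 1.89e-09), among them DCN (-5.29 ± 0.29), COL6A2 (-5.04 ± 0.26) and COL3A1 (-4.59 ± 0.34). The COL6A2 call was lost on its highest-mean suffix-free probe set (-0.46). Beside these groups, the list of fibroblast markers also fell, with 5 of 8 down and a median of -3.39 (adjusted p = 0.00345), although DCN, COL3A1, POSTN and other members belong to the matrix or mesenchymal lists too. THY1, a surface marker of fibroblasts, fell by 3.95 ± 0.22. Proteases and their inhibitors fell, 13 down and 2 up of 25 (median -1.22, adjusted p = 6.19e-05), led by TIMP3 (-5.14 ± 0.12), the gelatinase MMP2 (-5.00 ± 0.24) and the matrilysin MMP7 (-3.65 ± 0.14). Of 26 TGF-beta and BMP targets 12 fell and 2 rose (median -0.80, adjusted p = 2.62e-06), including SMAD6 (-3.27 ± 0.29), LTBP1 (-3.24 ± 0.08) and ID2 (-3.20 ± 0.12).

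Cholesterol and fatty acid synthesis rose in MIV against MIII, with 15 of 21 members up, 0 down and a median of 1.55 (camera adjusted p = 3.92e-15). HMGCS1 rose by 3.36 ± 0.09, the mevalonate decarboxylase MVD by 3.23 ± 0.10 and INSIG1 by 2.77 ± 0.06. IDI1 rose by 2.28 ± 0.07, a call that was lost on its highest-mean suffix-free probe set (0.18). Luminal epithelial genes rose as a list, 4 up and 1 down of 13 (median 0.88, adjusted p = 0.00146), with ERBB3 at 3.75 ± 0.31 and CD24 at 2.93 ± 0.07, while the mucin MUC1 fell by 1.40 ± 0.11. Oxidative stress genes fell, 7 down and 1 up of 24 (median -0.54, adjusted p = 0.000753), with MT1E at -4.58 ± 0.07 and the aldehyde dehydrogenase ALDH3A1 at -3.15 ± 0.19. The unfolded protein and amino acid stress list was called lower with 2 members down and 2 up of 23 (median -0.41, adjusted p = 0.00823), and the members that rose were ATF3 (2.37 ± 0.20) and TRIB3 (2.20 ± 0.07). ATF3 gave -0.40 on its highest-mean suffix-free probe set. All 10 lists named so far for this comparison as called kept their call with an estimated correlation.

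Another 6 lists were called in MIV against MIII with the preset correlation only. Desmosome genes rose, 4 up and 0 down of 14 (median 0.51, adjusted p = 5.39e-06), with DSC2 at 2.30 ± 0.08 and JUP at 2.19 ± 0.06, and had an adjusted p = 0.0568 with an estimated correlation. Antigen presentation fell, 4 down and 0 up of 18 (median -0.36, adjusted p = 0.0108), with HLA-C at -2.04 ± 0.05 and HLA-B at -2.02 ± 0.09, and also had an adjusted p = 0.0568 with an estimated correlation. MAPK output and EGFR ligands had 6 up and 0 down of 25 (median 0.27, adjusted p = 0.00848), among them the phosphatase DUSP5 at 1.73 ± 0.08, and an adjusted p = 0.14 with an estimated correlation. The p53 targets had 2 up and 1 down of 20 (median 0.17, adjusted p = 0.0108, and adjusted p = 0.136 with an estimated correlation), where GDF15 (1.22 ± 0.05) and MDM2 (1.14 ± 0.06) rose and the cell cycle inhibitor CDKN1A fell by 2.09 ± 0.06. With averaged probe sets GDF15 (0.69) and MDM2 (0.47) were short of 2-fold. Proliferation genes had no called member among 33 and a median of -0.18 (adjusted p = 0.0173, and adjusted p = 0.151 with an estimated correlation); the member with the smallest p was TYMS at -0.87 ± 0.05. Reported metastasis suppressors had 7 down and 2 up of 26 (median -0.35, adjusted p = 0.0221, and adjusted p = 0.133 with an estimated correlation), with TIMP3, the growth arrest gene GAS1 (-5.27 ± 0.31) and CDH11 (-3.35 ± 0.28) among those that fell. GAS1 gave -0.05 on its highest-mean suffix-free probe set.

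The other lists were not called in MIV against MIII. NF-kB cytokines and chemokines had 5 up and 7 down of 19 (median -0.10, adjusted p = 0.932), where CSF3 fell by 3.17 ± 0.33 and CXCL2 by 3.16 ± 0.14. Interferon response genes had 2 up and 7 down of 23 (median -0.38, adjusted p = 0.221), with IFI44L at -5.26 ± 0.21, and Wnt components 2 up and 6 down of 14 (median -0.44, adjusted p = 0.584). Keratinocyte differentiation had 6 up and 4 down of 23 (median 0.12, adjusted p = 0.179), with the kallikreins KLK5 and KLK6 up by 3.33 ± 0.07 and 2.22 ± 0.11. Basal genes had 3 up and 5 down of 15, with a median of 0.016, a mean of -0.12 and a test direction of up (adjusted p = 0.412), as KRT15 rose and KRT14 fell by 2.66 ± 0.11. Hypoxia and glycolysis had 2 up and 5 down of 28, with a median of 0.045, a mean of -0.21 and a test direction of up (adjusted p = 0.912). Cyclin-dependent kinase inhibitors had 1 down of 7, with a median of 0.07, a mean of -0.24 and a test direction of down (adjusted p = 0.413). Apoptosis regulators had 2 up of 27, with a median of -0.016, a mean of 0.09 and a test direction of up (adjusted p = 0.668). Integrins had 2 down of 15 (median -0.30, adjusted p = 0.252), leukocyte and endothelial markers 1 up of 5 (median 0.26, adjusted p = 0.932) and housekeeping controls no called member of 13, with a median of 0.045, a mean of -0.06 and a test direction of up (adjusted p = 0.932). Adjusted over the list alone, the number of called members was that over all genes in each of the 28 lists, except for the kinase inhibitors with 2 in place of 1. On suffix-free probe sets the fibroblast, antigen presentation and oxidative stress lists lost their calls (adjusted p of 0.34, 0.0721 and 0.0721), and the metastasis suppressors lost theirs with the stricter filter (0.106) or averaged probe sets (0.0903).

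**Figure D4:**
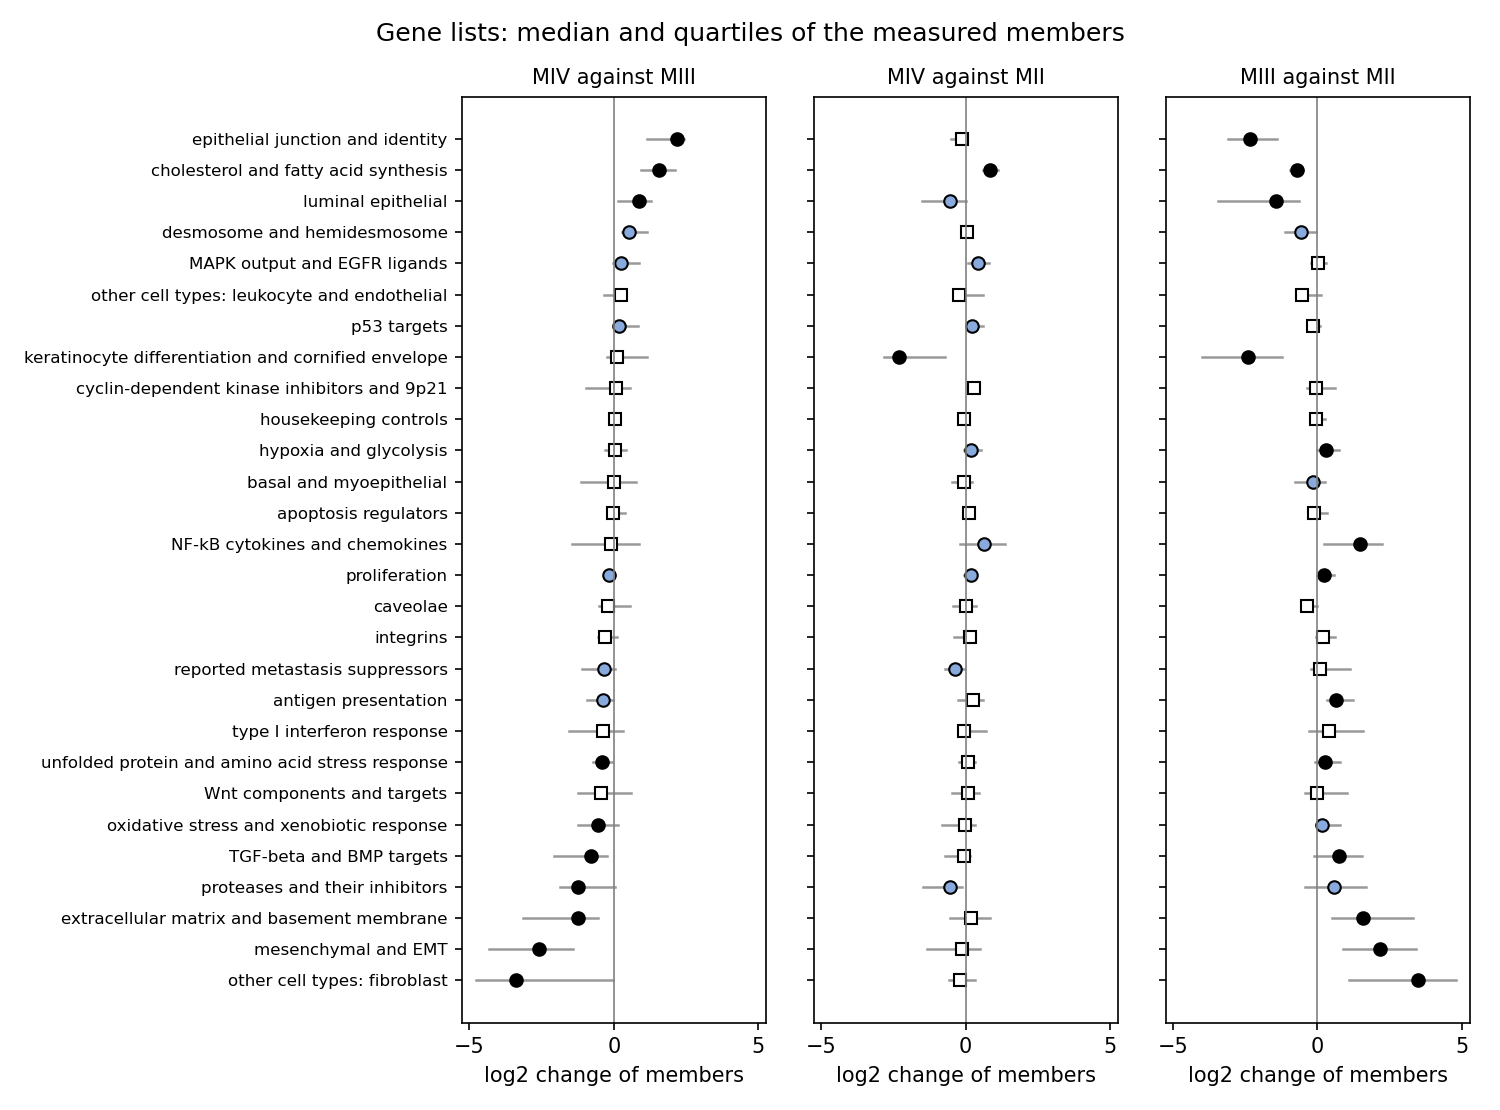
Median log2 change (marker) and quartiles (bars) of the tested members of 28 gene lists in the 3 comparisons; black circles are lists called by camera with the preset and with an estimated correlation, blue circles lists called with the preset correlation only, and white squares lists that were not called. The epithelial junction list lies at 2.18 in MIV against MIII and at -2.31 in MIII against MII, and the mesenchymal list at -2.59 and 2.17.

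MIV was also compared with MII, the line that represents carcinoma in situ. Keratinocyte differentiation was lower in MIV than in MII as a list (camera adjusted p = 2.26e-09), and cholesterol and fatty acid synthesis was higher (3.76e-12). The kallikrein KLK10 had a signal of 76.0 ± 32.0 in MIV and 19241 ± 829 in MII (SD, n = 3), a 214-fold fall on the offset scale. The log2 change was -7.27 ± 0.10 for PLAC8, -7.12 ± 0.13 for the kallikrein KLK7 and -6.99 ± 0.15 for the cytidine deaminase CDA. BST2, the tethering factor that holds budding viruses at the cell surface, rose from 6.2 ± 1.0, under the pooled median, to 1675 ± 119, or 69.1-fold on the offset scale. The intermediate filament VIM rose from 1291 ± 84.1 to 13557 ± 1108.

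Of the 12594 genes, 1025 were called between MIV and MII, 373 higher in MIV and 652 lower (63.6%). The share lower was 52.7% without a fold minimum, 55.3% under the filter at the pooled 75th percentile and 77.0% at an adjusted p under 0.01 and 4-fold. The arrays of the lines did not overlap in 98.9% of the called genes and 50.7% of all genes, where chance gives 10%. With the offset set to the pooled median, 681 genes were called. The other largest falls were those of TENT5B (-5.68 ± 0.28), MUC1 (-5.55 ± 0.11), MYADM, the guanine deaminase GDA (-5.41 ± 0.17), WFDC2 (-5.25 ± 0.10) and CAVIN2. Besides LOC389831, PDE1C, IL13RA2 and RNF128, the largest rises included the protease PRSS21 (5.09 ± 0.30), the chaperone partner BAG2 (4.62 ± 0.12) and the inositol synthase ISYNA1 (3.95 ± 0.23). The cytokine IL1A rose by 3.63 ± 0.20 on the probe set used, but its highest-mean suffix-free probe set gave 0.18.

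A pair of lists was called in MIV against MII with either correlation. Cholesterol and fatty acid synthesis rose, 7 up and 0 down of 21 (median 0.84, camera adjusted p = 3.76e-12, and adjusted p = 0.0159 with an estimated correlation), with HMGCS1 up by 2.54 ± 0.09, INSIG1 by 2.15 ± 0.06 and MVD by 1.43 ± 0.10. Keratinocyte differentiation fell, 16 down and 1 up of 23 (median -2.28, adjusted p = 2.26e-09, and adjusted p = 0.0159 with an estimated correlation), led by KLK10, KLK7, KLK6 (-4.09 ± 0.11) and the serpin SERPINB3 (-3.87 ± 0.10).

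A further 8 lists were called in MIV against MII with the preset correlation only. MAPK output and EGFR ligands had 4 up and 0 down of 25 (median 0.42, adjusted p = 4.83e-06, and adjusted p = 0.0692 with an estimated correlation), with the EGFR ligand EREG at 1.60 ± 0.07 and the early response factor EGR1 at 1.25 ± 0.06. NF-kB cytokines had 8 up and 1 down of 19 (median 0.63, adjusted p = 0.00215, and adjusted p = 0.0692 with an estimated correlation), with CXCL8 up by 3.06 ± 0.06 and IL1B by 2.33 ± 0.11, while the lipocalin LCN2 fell by 2.83 ± 0.09. Hypoxia and glycolysis had 5 up and 0 down of 28 (median 0.18, adjusted p = 0.00215, and adjusted p = 0.0692 with an estimated correlation), with VEGFA at 1.73 ± 0.07 and BNIP3 at 1.70 ± 0.06. The p53 targets had 2 up and 1 down of 20 (median 0.24, adjusted p = 0.00961, and adjusted p = 0.152 with an estimated correlation), and the member that fell was CDKN1A at -2.40 ± 0.06. Proteases and their inhibitors had 8 down and 3 up of 25 (median -0.53, adjusted p = 0.0107, and adjusted p = 0.106 with an estimated correlation), with TIMP3 at -4.22 ± 0.12 and the urokinase PLAU at 1.95 ± 0.12. Luminal genes had 5 down and 0 up of 13 (median -0.55, adjusted p = 0.0224, and adjusted p = 0.118 with an estimated correlation), including MUC1 and CD24 (-1.95 ± 0.07). Reported metastasis suppressors had 2 down and 2 up of 26 (median -0.35, adjusted p = 0.0166, and adjusted p = 0.143 with an estimated correlation): TIMP3 and PLAAT4 (-1.24 ± 0.23) fell, and the scaffold AKAP12 (2.67 ± 0.08) and NDRG1 (1.70 ± 0.09) rose. PLAAT4 was short of 2-fold with the offset set to the pooled median (-0.78). Proliferation genes had no called member of 33 and a median of 0.19 (adjusted p = 0.0227, and adjusted p = 0.191 with an estimated correlation), a call that was also lost with quantile normalization (adjusted p = 0.102) and with cyclic loess (adjusted p = 0.1).

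The epithelial junction list was not called in MIV against MII, with 2 of 22 down and a median of -0.13 (adjusted p = 0.0604). The mesenchymal and EMT list had members on both sides, 5 up and 7 down of 22 (median -0.11, adjusted p = 0.857): VIM rose by 3.37 ± 0.06 and fibronectin FN1 by 3.16 ± 0.13, whereas S100A4 fell by 3.77 ± 0.10 and TWIST2 by 2.77 ± 0.12. The FN1 call was lost on its highest-mean suffix-free probe set (0.27). The extracellular matrix list had 6 up and 2 down of 30 (median 0.20, adjusted p = 0.174), with the fibrillin FBN2 at 2.51 ± 0.08, and the fibroblast markers beside it had 1 up of 8, FBLN1 at 1.54 ± 0.16 (median -0.18, adjusted p = 0.837). FBLN1 was short of 2-fold with averaged probe sets (0.94). Also not called were TGF-beta and BMP targets with 3 up and 6 down of 26 (median -0.05, adjusted p = 0.599), among them TGFB2 at -3.04 ± 0.16, and oxidative stress genes with 1 up and 5 down of 24 (median -0.003, mean -0.46, adjusted p = 0.726). Interferon response genes had 4 up and 3 down of 23, with a median of -0.05, a mean of 0.17 and a test direction of up (adjusted p = 0.726), as BST2 rose and OAS1 fell by 3.32 ± 0.15. Antigen presentation had 2 up and 1 down of 18 (median 0.25, adjusted p = 0.341), with PSMB9 at 1.66 ± 0.11. Basal genes had 2 down of 15, KRT16 (-4.04 ± 0.12) and KRT14 (-3.82 ± 0.11), with a median of -0.04 (adjusted p = 0.829), and integrins 1 up and 2 down of 15 with a median of 0.15, a mean of -0.22 and a test direction of up (adjusted p = 0.296). Wnt components had 1 up and 2 down of 14 (median 0.09, mean -0.08, direction up, adjusted p = 0.837), apoptosis regulators 2 up and 1 down of 27 (median 0.13, adjusted p = 0.138) and stress response genes 2 up of 23 (median 0.10, adjusted p = 0.599). Desmosome genes had no called member of 14 (median 0.05, adjusted p = 0.726), nor had the 13 housekeeping controls, with a median of -0.04 and a test direction of up (adjusted p = 0.829). Kinase inhibitors had 1 down of 7 (median 0.30, mean -0.10, direction up, adjusted p = 0.837) and leukocyte and endothelial markers 1 down of 5, CD14 at -2.15 ± 0.10 (median -0.23, adjusted p = 0.841). Adjusted over the list alone, the number of called members was that over all genes in each list except keratinocyte differentiation, with 18 in place of 17. On suffix-free probe sets, calls of the luminal (adjusted p = 0.308), NF-kB (0.0574), hypoxia (0.177), metastasis suppressor (0.177) and proliferation (0.3) lists were lost.

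MIII was compared with MII as the background for both comparisons with MIV. MIII had low levels of epithelial genes and high levels of mesenchymal and matrix genes relative to MII. The matrix protein SPARC had a signal of 13671 ± 812 in MIII and 33.8 ± 2.4 in MII (SD, n = 3), a 263-fold rise on the offset scale. CLDN7 had 23.5 ± 21.8 in MIII and 10233 ± 361 in MII, a 266-fold fall on that scale. FN1 rose by 7.85 ± 0.13 in log2, FABP4 by 7.55 ± 0.24 and IGFBP4 by 7.36 ± 0.31, and the adhesion gene CEACAM6 fell by 6.10 ± 0.11.

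Of the 12594 genes, 1476 were called between MIII and MII, 777 higher in MIII and 699 lower (47.4%). The balance turned with the filter at the pooled 75th percentile (391 higher, 419 lower), without a fold minimum (2880 and 3066) and with averaged probe sets (559 and 578). The arrays did not overlap in 99.3% of the called genes and 55.3% of all genes, where chance gives 10%. The other largest rises were those of SRGN, CD36, COL6A1, BST2, ENPP2 and GNG11, between 7.16 and 5.95. The other largest falls were those of PSCA, the amino acid transporter SLC6A14, KLK7, KLK10, GABRP, KLK6, the protease inhibitor A2ML1 and RAB25, between -7.93 and -5.74. Of the genes called here, 512 were higher in MIII than in MII and lower in MIV than in MIII. In the other direction, 367 were lower in MIII than in MII and higher in MIV than in MIII. Independent lists of the same lengths would share 60.5 and 34.6 genes. Simulated unchanged groups gave 0 of either in 100 simulations, but no gene was changed there and almost no calls arose. Both comparisons share the MIII arrays with opposite signs, so part of the excess may come from the shared arrays.

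The epithelial junction list fell in MIII against MII, with 19 of 22 down, 0 up and a median of -2.31 (camera adjusted p = 4.35e-20), including CLDN7, RAB25 (-5.74 ± 0.07), CLDN4 (-5.58 ± 0.18) and OCLN (-4.71 ± 0.25). The mesenchymal and EMT list rose, 15 up and 1 down of 22 (median 2.17, adjusted p = 6.5e-14), with POSTN at 5.55 ± 0.27 and VIM at 4.75 ± 0.06. The extracellular matrix list rose, 18 up and 1 down of 30 (median 1.58, adjusted p = 1.17e-12), with COL6A1 at 6.88 ± 0.32 and COL3A1 at 4.87 ± 0.34. Beside these groups the fibroblast markers rose as well, 6 up and 0 down of 8 (median 3.48, adjusted p = 0.00125), with THY1 at 3.71 ± 0.22. Keratinocyte differentiation fell, 17 down and 3 up of 23 (median -2.38, adjusted p = 5.84e-08), and luminal genes fell, 7 down and 0 up of 13 (median -1.43, adjusted p = 8.49e-08), with CD24 at -4.88 ± 0.07 and ERBB3 at -4.14 ± 0.31. Cholesterol and fatty acid synthesis fell, 3 down and 0 up of 21 (median -0.68, adjusted p = 1.78e-09), the members being MVD (-1.80 ± 0.10), SREBF1 (-1.12 ± 0.12) and SC5D (-1.06 ± 0.07, but -0.94 on its highest-mean suffix-free probe set, where the call was lost). NF-kB cytokines rose, 11 up and 2 down of 19 (median 1.47, adjusted p = 4.86e-05), with the chemokine CXCL1 at 3.39 ± 0.11 and IL6 at 2.77 ± 0.43. Antigen presentation rose, 7 up and 0 down of 18 (median 0.65, adjusted p = 5.57e-05), with the immunoproteasome subunit PSMB9 at 2.65 ± 0.11. TGF-beta and BMP targets rose, 11 up and 1 down of 26 (median 0.76, adjusted p = 8.03e-05), with TGFB1 at 3.53 ± 0.09 and LTBP1 at 2.99 ± 0.08.

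Smaller shifts were called in MIII against MII for proliferation, with KIF20A (1.02 ± 0.09) and FOXM1 (1.03 ± 0.07) up of 33 (median 0.22, adjusted p = 7.39e-05), and for hypoxia and glycolysis, with 7 up of 28 (median 0.29, adjusted p = 0.000677) and the collagen crosslinker LOX at 3.06 ± 0.12. The KIF20A call was lost without MII replicate 2 (0.94) or MIII replicate 2 (0.98), and that of FOXM1 without MII replicate 1 (0.96) or MIII replicate 1 (0.98). The stress response list rose with 3 up of 23 (median 0.26, adjusted p = 0.00582), with the hormone STC2 at 1.89 ± 0.09. These 13 lists kept their calls with an estimated correlation. Desmosome genes fell, 4 down of 14 (median -0.55, adjusted p = 9.11e-05, and adjusted p = 0.0823 with an estimated correlation), with DSC2 at -3.05 ± 0.08 and JUP at -2.26 ± 0.06. Oxidative stress genes had 3 up and 1 down of 24 (median 0.18, adjusted p = 0.00496, and adjusted p = 0.0682 with an estimated correlation), with the steroid reductase AKR1C3 at 1.99 ± 0.05 and ALDH1A3 at -2.12 ± 0.05. Proteases and their inhibitors had 8 up and 3 down of 25 (median 0.57, adjusted p = 0.0311, and adjusted p = 0.0928 with an estimated correlation), with SERPINE2 at 3.76 ± 0.06 and the cathepsin CTSV at -3.49 ± 0.05. Basal genes had 3 up and 3 down of 15 (median -0.16, adjusted p = 0.0317, and adjusted p = 0.166 with an estimated correlation), with KRT15 at -5.52 ± 0.07 and the membrane protease MME at 3.15 ± 0.39.

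The remaining lists were not called in MIII against MII. Interferon response genes had 6 up and 2 down of 23 (median 0.41, adjusted p = 0.126), with BST2 at 6.68 ± 0.11 and OAS2 at 3.99 ± 0.32. Reported metastasis suppressors had 7 up and 2 down of 26 (median 0.09, adjusted p = 0.22), where the cadherin CDH1 fell by 3.19 ± 0.05 and GAS1 rose by 4.79 ± 0.31 but gave -0.21 on its highest-mean suffix-free probe set. Integrins had 3 up and 2 down of 15 (median 0.21, adjusted p = 0.0668), with ITGA5 at 2.09 ± 0.07 and ITGB2 at -2.39 ± 0.16, and Wnt components 4 up and 2 down of 14 (median 0.005, adjusted p = 0.598), with TNFRSF19 at 3.68 ± 0.32. MAPK output had 3 up of 25 (median 0.03, adjusted p = 0.569), and apoptosis regulators 1 up and 1 down of 27, with a median of -0.10 and a test direction of up (adjusted p = 0.736). Kinase inhibitors had 1 up of 7, CDKN1C at 1.25 ± 0.22, with a median of -0.03, a mean of 0.14 and a test direction of up (adjusted p = 0.42). CDKN1C was short of 2-fold with the offset set to the pooled median (0.99). Leukocyte and endothelial markers had 1 down of 5 (median -0.54, adjusted p = 0.37). No member was called of 20 p53 targets (median -0.15, adjusted p = 0.345) or of 13 housekeeping controls, with a median of -0.06, a mean of 0.06 and a test direction of up (adjusted p = 0.676). Adjusted over the list alone, the number of called members was that over all genes in each of the 28 lists. On suffix-free probe sets, calls of the TGF-beta (adjusted p = 0.087), hypoxia (0.105), oxidative stress (0.051) and protease (0.602) lists were lost, and that of the basal list was lost with an untrended variance prior (0.0724).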

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

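Tests chosen only after the result was seen were those of the second probe sets of lost genes, of dilution by fibroblasts, of scaling in MIII, of an inverse relation of sterol genes to ACAT2 and of whole lines in turn as the odd group. The tests of second probe sets and of fibroblasts replaced earlier ones that had left the matter undecided: 53.5% of second probe sets carried the call (Wilson 95% interval 38.9 to 67.5), and of COL1A1, COL1A2, COL3A1 and LUM, abundant transcripts of fibroblasts, 1 lay over the pooled 75th percentile in MIII (COL3A1, 652.5) and 1 under the pooled median (COL1A2, 26.0).

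In data outside the comparisons by gene, 70 probe sets without a single named gene were lower in MIV than in both other lines, and 31 were higher. Of such probe sets 5142 were tested, and they were counted because no comparison of named genes used them.

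The first pattern is the loss of 123 genes at the floor in MIV, CAVIN2 among them. The loss of chromosome segments as the whole cause is argued against by the immediate tested neighbours of lost genes. The 236 neighbours that were not lost themselves had a median log2 change of -0.107 against MIII and -0.055 against MII. Neighbours that were lost too were left out of these medians, and genes that failed the filter were not seen. Segments stay open as part of the cause: 6 lost genes were adjacent to another, against 2.31 in random sets (permutation p = 0.11), 11 lost genes lie in the stretch from CEP89 to ZNF324, where 4.3 would without regard to place, although that stretch was picked for its low genes, and of all genes lower in MIV than in both lines 37 were adjacent to another, against 14.05 in random sets (permutation p = 2e-04). A fault of single probe sets as the general cause is argued against for the 43 of 123 lost genes that had a second tested probe set. Of these second probe sets 86% (37 of 43, Wilson 95% interval 72.7 to 93.4) were lower in MIV in both comparisons, against 35.7% among uncalled genes. The lost genes without a second tested probe set are not covered. A biological difference between the lines, such as silencing of single genes, may account for the losses and stays an untested hypothesis.

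The second pattern is the mesenchymal state of MIII. For fibroblasts mixed into the cultures, the desmosome list had a median of -0.548 in MIII against MII, and the epithelial junction list -2.311. These medians cannot decide it, since members that fibroblasts also express would not be diluted. Of the 14 desmosome members 4 fell, among them DSC2 (5787 ± 143 in MII, 686 ± 88.5 in MIII), and 10 were not called. A line that expresses the 9p21 genes under the MIII label is argued against by their highest mean in MIII, 88.2 for MTAP, below the pooled 75th percentile, but a line that also lacks them stays open. Scaling between arrays is argued against by the housekeeping median of -0.058. A state of the MIII cells themselves may be the source, a hypothesis that these arrays alone do not settle.

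The third pattern is the rise of sterol synthesis genes in MIV while ACAT2, which feeds the same pathway, fell. That sterol genes follow ACAT2 inversely across the lines is argued against by MIII, where ACAT2 was lower than in MII (-0.97 ± 0.12) and the list median was lower too (-0.684). Scaling is argued against by a lowest median of 0.885 in MIV against MII under the other scalings. Whether the ACAT2 fall may come from a fault of its probe set cannot be told apart from a real fall, since only 1 ACAT2 probe set was over the pooled median in MII and called. A response of the pathway to low ACAT2 in MIV alone stays open as a hypothesis.

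For the comparisons of a line with another, 3 arrays against 3 make 10 splits, too few for a share under 0.05. The real splits, 1 of 10 in each, called 1604, 1025 and 1476 genes and the highest of the others called 0. Of 100 splits of the 9 arrays drawn at random, the real one included, 1 gave as many genes lower than both other groups (302, highest other in the draw 164). At the floor 1 gave as many (123, highest other 37), and 3 gave as many higher (125, highest other 260). Splits whose odd group mixed lines gave 0, since mixing lines widens the spread within groups. These shares therefore cannot decide on a random grouping. Large counts came with whole lines as the odd group, a structure of the lines: MII, which was in the draw, gave 164 lower and 260 higher, and MIII, which was not, gave 367 lower, 512 higher and 70 at the floor. A count as large as that of MIV is thus not particular to MIV for genes lower or higher than both, while the 123 at the floor exceeded those of the other lines. The floor is a pooled median, and MIV arrays had the lowest medians (64.7 to 65.2, against 69.0 to 74.9), which may raise the MIV count. Of the 123 genes, 103 stayed with quantile normalization and 98 with cyclic loess, where the other lines were not recounted.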

How the results depend on the processing

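No alternative was added after the data were seen. CAVIN2 kept its direction and its call in MIV under every alternative run for it, between -5.89 and -3.01 against MIII and between -6.80 and -3.84 against MII. Of 6868 results of named genes under alternatives, 6789 kept their call or stayed uncalled, 72 lost the call, 3 gained it and 4 reversed. The direction of results that stayed uncalled was not followed, and genes that an alternative dropped were not counted under it. Of 1032 results of the called lists, 991 kept the call and 41 lost it, while lists not called at first were not followed. The reversed values came from the highest-mean suffix-free probe set, which is another probe set of the gene: AGMAT gave 0.20 against MII and 0.21 against MIII, ATF3 gave -0.40 in MIV against MIII and GAS1 gave -0.21 in MIII against MII. The filter at the pooled 75th percentile, which tests fewer genes, gave 893, 535 and 810 called genes in MIV against MIII, MIV against MII and MIII against MII, with 138 lower than both and 29 at the floor. Without a fold minimum, which admits smaller changes, 6530, 5310 and 5946 genes were called, 1569 were lower and 1470 higher than both. At an adjusted p under 0.01 and 4-fold, a stricter threshold, 515, 257 and 499 were called, with 71 lower, 14 higher and 38 at the floor. An offset at the pooled median, which shrinks changes of dim genes, gave 681 genes in MIV against MII, with 164 lower, 83 higher and 55 at the floor. Lists called with an estimated correlation numbered 10 in MIV against MIII and 2 in MIV against MII, and fry, which does not compare a list with other genes, called 26, 25 and 26. In MIV against MII, averaged probe sets called 6 lists and suffix-free probe sets 5, and the cause was not tested. Leaving out each array in turn gave 1563 to 1619, 1001 to 1031 and 1449 to 1487 called genes, 290 to 326 lower, 117 to 125 higher and 118 to 142 at the floor, CAVIN2 between -4.48 and -3.98 and between -5.37 and -4.87, and 16 to 16, 10 to 11 and 17 to 18 lists. Without MIV replicate 3, whose spike-ins were high, 1563, 1001 and 1478 genes were called and 298 were lower than both. Replicate numbers did not pair arrays of different lines, since residuals of the same number correlated at a median of -0.001 (9 pairs) and of other numbers at 0.001 (18 pairs), and with a block for the number 1607, 1026 and 1483 genes were called, of which 1598, 1019 and 1474 were shared with the fit without it. Signal near background limits the values of genes at the floor.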

Other observations

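The test on stretches of neighbouring genes was chosen only after the result was seen, and so were the genes named in this part.

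Genes that fell from MII to MIII and again from MIII to MIV numbered 34, and 7 rose at both steps. A step here is a difference between lines ordered by their stage labels, not a change over time. Independent lists of the same lengths would share 54.4 and 38.4 genes, so both counts lay below that overlap. The MIII arrays, shared by both steps with opposite signs, lower such counts. Simulated unchanged groups gave 0 of either in 100 simulations, but no gene was changed there and almost no calls arose. CDA, which deaminates cytidine, went from 2664 ± 46.8 in MII to 174 ± 29.3 in MIII and 2.8 ± 0.3 in MIV (SD, n = 3). The keratin KRT14 went from 2155 ± 85.4 to 957 ± 84.5 and 137 ± 20.4, and S100A4 from 3386 ± 170.1 to 1149.5 ± 36.9 and 232.9 ± 36.1. The genes that rose at both steps were BAG2, CXCL8, IL13RA2, IL1A, PDE1C, PLD1 and TSPAN5, of which IL1A lost its call in MIV against MII on its highest-mean suffix-free probe set (0.18). BAG2 went from 116 ± 28.3 to 1525 ± 37.1 and 3238 ± 122, and CXCL8 from 857 ± 62.0 to 3563 ± 207 and 7261 ± 125.

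Some stretches of neighbouring genes were shifted together, in windows of 41 tested genes compared with 1000 shuffles of gene order. A stretch runs from the first to the last window on a chromosome whose median lay outside the limits set by the shuffles. Windows between them can lie within these limits, so a stretch need not be shifted throughout. The 641 genes from KDM5A to SBNO1 had a median log2 change of 0.415 in MIII against MII and of -0.015 in MIV against MII. The 371 genes from RYBP to NCBP2 had medians above those of MII both in MIII (0.329) and in MIV (0.421). In MIII against MII, 8 windows of this stretch lay outside the limits. The 441 genes from CEP89 to ZNF324 had a median of -0.435 in MIV against MII and -0.436 against MIII. Other stretches were higher in MIV than in both lines: the 451 genes from ZMYND11 to WDR11 had medians of 0.267 against MII and 0.345 against MIII, and the 71 genes from DOCK8 to CHMP5 had 0.376 and 0.44. The uncalled genes of the longest stretch had a median of 0.331, which tests no explanation, since the stretches were picked by the medians of their windows. A gain or loss of copies of these segments may account for such shifts, a hypothesis left untested, as DNA copy number was not analysed here.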
